A study of Brassica rapa with 12 samples.

How the data were processed

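RNA from whole seedlings of *Brassica rapa* was sequenced in 12 libraries, with 3 libraries for each combination of line (Chiifu or LP08) and light treatment. Per the labels' protocols, RNA was extracted with an RNeasy kit, treated with DNase I and made into libraries with the TruSeq Stranded mRNA kit. The deposited files hold 1 table of read counts per library, with 1 whole number per feature and a different total in each library, so they are raw counts that the authors did not normalize. The submitters' processing notes name FastQC, TopHat2, featureCounts and edgeR, without versions and without saying which step each performed. The genome build, the gene annotation, the strand setting and any filter are not given in the sources used here. Each table lists the same 42186 features, of which 41018 have an ID that starts with Bra and 1168 an ID that starts with ENSRNA, the prefix Ensembl uses for non-coding RNA genes. No row holds unassigned reads or a total, and 4286 features had a count of 0 in all 12 libraries.

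The files do not pair the IDs with gene names. The RefSeq gene table of assembly CAAS_Brap_v3.01 was searched over its gene IDs, locus tags, symbols, synonyms and Ensembl IDs, and 1 of the 42186 IDs was found in it, Bra000116, which carries the synonym SWEET9. The 26 lists of Arabidopsis genes (glucosinolate synthesis, breakdown and regulation, photosynthesis, light signalling, flavonoids, clock, hormones, root and seed markers) that were fixed before the data were examined could not be joined to the counts, and no gene list was tested. The part of the study on quantitative trait loci was not analysed here. For the same reason IDs are reported without positions, and it could not be checked whether a reported gene shares reads with a near-identical copy, an overlapping gene or an antisense gene.

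Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with the group as its argument, at its minimum count of 10 and minimum total of 15, which left 31239 tested features (31088 Bra and 151 ENSRNA), called genes below. Libraries were scaled by the trimmed mean of M values (TMM), dispersions were estimated with a mean per group over all 12 libraries, and contrasts were tested with the robust quasi-likelihood F-test. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is the one implied by its F statistic. CPM values given for genes, and the bounds on folds, use the TMM-scaled library total. Thresholds for features at 1 CPM or more, for genes on in one group and without reads in another, for genes seen in 1 line only (1 or 5 CPM) and for the stricter filter use the unscaled total. There were 5 comparisons: LP08 against Chiifu in light and in dark, light against dark in Chiifu and in LP08, and the difference of the light responses. A fold against a group with no reads is a lower bound, computed against 3 counts over the 3 libraries of that group. It covers counting error in that group only, since the reads have no molecular identifiers. The mean of the other group is taken as exact, so the spread between its libraries is not covered.

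The rule for the genes given by ID was fixed before the data were examined: because the IDs could not be named, the 2 genes higher and the 2 lower with the largest fitted log2 fold change in each comparison, among called genes with a mean of at least 10 CPM in the higher group and, for a comparison of 2 groups, no overlap between their replicates. A gene seen in 1 line only had a count of 0 in all 6 libraries of the other line and at least 1 CPM in all 6 of its own. Measures of library composition (features detected, features at 1 CPM or more, share of counts in the 10 and 100 most abundant features, share in ENSRNA features) were compared with exact two-sided permutation tests over the 400 arrangements that exchange labels within the other factor, and adjusted over the 10 tests.

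Library totals ranged from 48773088 to 71764062 counts. A count of 0 allows up to 3 counts, which is 0.0615 CPM of the unscaled total in the smallest library. The labels do not say whether replicates came from separate plants or cultures, so p-values measure the spread between these libraries, which may be partly technical. Every within-group pair differed by more than counting noise, with a chi-square per degree of freedom of at least 13.7 over genes with 10 or more counts in the pair, so none was treated as a repeated library. Replicates carry the numbers 1 to 3 in each group. Of the 18 pairs of libraries that share a number across groups, 8 had deviations from their group means that correlated above 0.1, and the range was -0.25 to 0.30, so the numbers were not taken to pair the samples.

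The procedure was tested on simulated data with the real library sizes and dispersions and a single mean per gene over all 12 libraries. In each comparison 200 genes were changed. The real data had far more calls (14489 for LP08 against Chiifu in light), which loosens the cut-off on the unadjusted p. The shares recovered below therefore do not measure the sensitivity of the real tests. For LP08 against Chiifu in light, with 30615 genes in the step, 76.5% of genes changed 4-fold, 29.9% of those changed 2-fold and 3.08% of those changed 1.5-fold were recovered, with 6 false calls among 80. For the difference of the light responses, with 30630 genes, the shares were 54.7%, 2.99% and 0%, with 1 false call among 32. The alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, a fit on only the libraries compared, and leaving out each library. Library totals without composition scaling, removal of ENSRNA features, removal of both libraries that stood apart from their groups, thinning of all libraries to the smallest total, and, for response differences of genes given by ID, raising group levels under 1% of the highest group to that level were added after the data had been seen.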

Results

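The transcriptomes of 2 *Brassica rapa* lines were measured in 1-week-old whole seedlings. Chiifu is a Chinese cabbage line, and the RefSeq assembly of the species is from Chiifu-401-42. LP08 is the other line, and the series title sets a vegetable type against an oilseed type of the species and names glucosinolates, the sulfur-rich defence compounds of the cabbage family, as its subject. Light seedlings had 16 h of light and 8 h of dark, and dark seedlings 24 h of dark. The labels do not say whether the dark treatment lasted the whole week. Each of the 4 groups had 3 libraries. Mean total counts were 55356085 ± 5812506 in dark Chiifu, 70034296 ± 1543335 in light Chiifu, 50954536 ± 3278509 in dark LP08 and 59402561 ± 3825453 in light LP08 (SD, n = 3 each). Genes are given by ID because the files do not pair the IDs with names. The 1 ID that could be matched, Bra000116 (SWEET9, a member of the SWEET sugar transporter family), had no read in any of the 12 libraries, which allows up to 0.00424 CPM of their unscaled totals together.

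The 4 groups separated fully. The first principal component of log2 CPM, with 45.3% of the variance, and the second, with 39.8%, placed the 4 groups in 4 corners. Within-group correlations across genes were 0.962 to 0.990 and between-group correlations 0.678 to 0.844. The lowest mean correlations with their own group were those of Chiifu dark replicate 3 (0.965) and LP08 light replicate 3 (0.972), and each of the other 10 libraries had 0.973 or more.

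**Figure D1:**
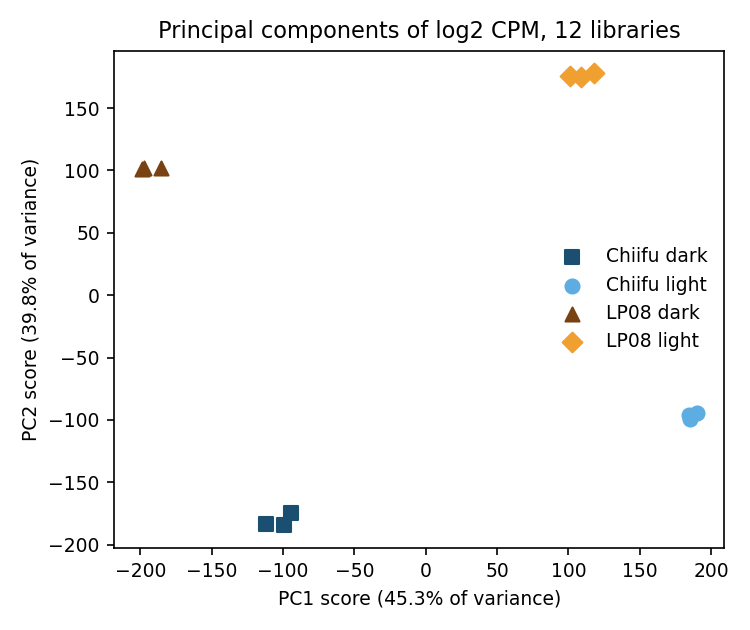
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM over 31239 genes; each point is a library. The 4 groups form separate clusters, with dark libraries at negative and light libraries at positive values of the first component within each line, and Chiifu at negative and LP08 at positive values of the second.

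The most abundant transcripts differed more between light and dark than between the lines. Of the 100 most abundant features of a group, 81 were shared between the lines in light and 71 in dark, whereas 19 were shared between light and dark in Chiifu and 16 in LP08. The 10 most abundant features held 7.58 ± 0.80% of counts in light Chiifu and 9.19 ± 0.68% in light LP08, against 4.097 ± 0.44% and 5.79 ± 0.59% in the dark (SD, n = 3). The difference between light and dark was 3.44 percentage points, with an exact two-sided permutation p = 0.005, the smallest that the 400 arrangements allow, and an adjusted p = 0.0125. LP08 was higher than Chiifu by 1.65 percentage points, with the same exact p and adjusted p. Fewer features had at least 1 CPM in LP08 than in Chiifu, with a difference of means of -842 (LP08 minus Chiifu, exact permutation p = 0.015, adjusted p = 0.03). The gap was larger in light, with 23743 ± 343 in LP08 and 25000 ± 194 in Chiifu. In the dark the values were 23737 ± 117 and 24163 ± 363 (SD, n = 3). The threshold uses the unscaled total, and the count with scaled totals was not tested. ENSRNA features took 0.557% to 2.90% of counts, with the highest share in Chiifu dark replicate 3, and the difference did not pass the test by light (exact p = 0.115, adjusted p = 0.144) or by line (exact p = 0.335, adjusted p = 0.335).

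The first question was how each line's transcriptome differed between light and dark. In Chiifu, 10586 genes were higher and 10500 lower in light, together 67.5% of those tested. Which direction held more genes depended on the setting, with 10321 higher and 10821 lower with DESeq2 size factors, 9672 and 11356 with library totals, and 9865 and 9921 without Chiifu dark replicate 1. By at least 2-fold, 7865 were higher and 6188 lower. Genes higher by at least 2-fold in light rose from 11.03 ± 1.49% of all counts in the dark to 48.5 ± 1.38% in light, and genes lower by at least 2-fold fell from 41.0 ± 1.46% to 9.44 ± 0.36% (SD, n = 3); these genes were picked on the same libraries. Among genes that met the rule for naming, Bra008024 and Bra003696 had the largest fitted increases. Neither had a read in dark Chiifu, and they reached 21.5 ± 6.68 and 26.2 ± 32.0 CPM in light, at least 1300-fold and at least 1580-fold higher (edgeR adjusted p = 7.68e-07 and 0.00151). The value of Bra003696 rested largely on Chiifu light replicate 2, with 63.0 CPM against 10.7 and 4.91 CPM in the others. Its bound of 1580-fold is for the mean and does not cover this spread. Bra027681 and Bra024080 had the largest decreases, from 23.3 ± 5.53 and 11.5 ± 1.12 CPM in the dark to no read in light, at least 1640-fold and at least 810-fold lower (adjusted p = 5.61e-08 and 6.12e-08). In all, 29 genes had at least 1 CPM in every light library and no read in the dark, and 33 the opposite.

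In LP08, 10328 genes were higher and 11072 lower in light, 68.5% of those tested, and 7740 and 7276 by at least 2-fold. With library totals in place of TMM scaling the last 2 counts were 6753 and 8703, so the balance turned. Genes higher by at least 2-fold rose from 12.2 ± 1.67% to 56.9 ± 2.51% of counts, and those lower by at least 2-fold fell from 45.5 ± 1.42% to 9.40 ± 1.17% (SD, n = 3), again picked on the same libraries. The largest decrease was that of an abundant transcript, Bra001843, which fell from 18110 ± 3502 CPM in the dark to 1.49 ± 0.14 CPM in light, a 12200-fold difference of means (log2 fold change -13.57, SE 0.435, adjusted p = 1.18e-09). In Chiifu the same gene was at 1031 ± 273.5 CPM in the dark and 35.4 ± 10.4 CPM in light. Bra022636 went from 17.39 ± 3.30 CPM to no read, at least 921-fold lower (adjusted p = 5.01e-06). Bra001761 and Bra018521 had no read in dark LP08 and 56.5 ± 1.25 and 25.8 ± 3.17 CPM in light, at least 2950-fold and at least 1350-fold higher (adjusted p = 1.85e-06 and 1.57e-06). There were 18 genes on in light with no read in the dark, and 48 the opposite.

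**Figure D2:**
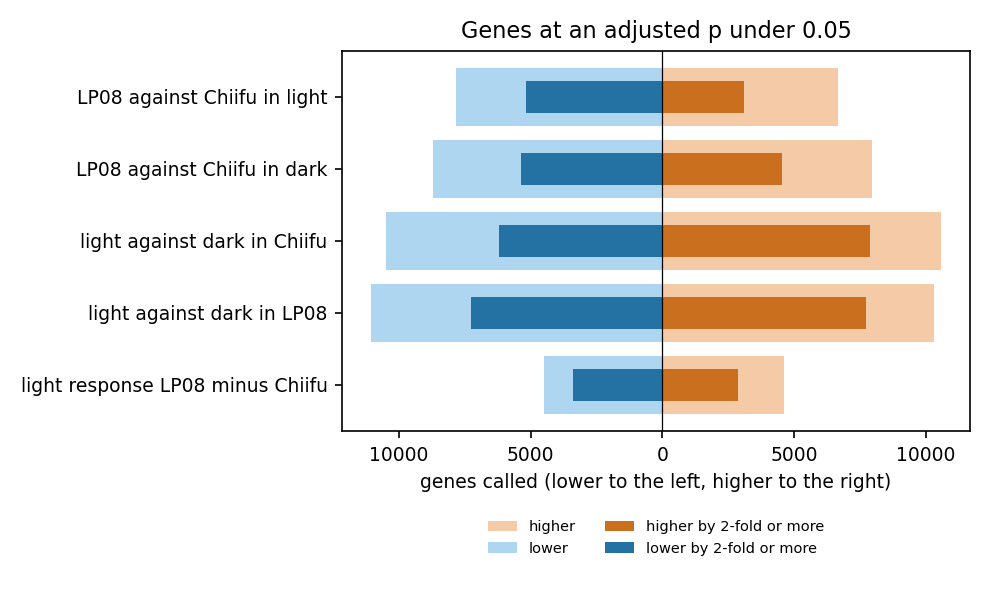
Number of genes called at an adjusted p under 0.05 (x axis) in each of the 5 comparisons (y axis), lower to the left and higher to the right; the narrow bars are the genes that differ by at least 2-fold. The light comparisons hold the most genes (10586 higher and 10500 lower in Chiifu), and in light 3098 genes are higher and 5168 lower by at least 2-fold in LP08.

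More genes were called with light in both lines than in one alone: 16436 in both, 4650 in Chiifu only and 4964 in LP08 only. Of those called in both, 94.5% changed in the same direction, with 7626 higher and 7912 lower, and 898 changed in opposite directions. Of the genes called in either line, 83.1% had a fold change of the same sign in both. Independent lists of these sizes would share 3500 higher, 3722 lower and 7223 opposite genes. The 2 comparisons have no library in common, but they share a fit and the dispersion of each gene. Being called is thus not independent between them, whether or not the responses are shared. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.71 and Spearman's rho = 0.72.

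**Figure D3:**
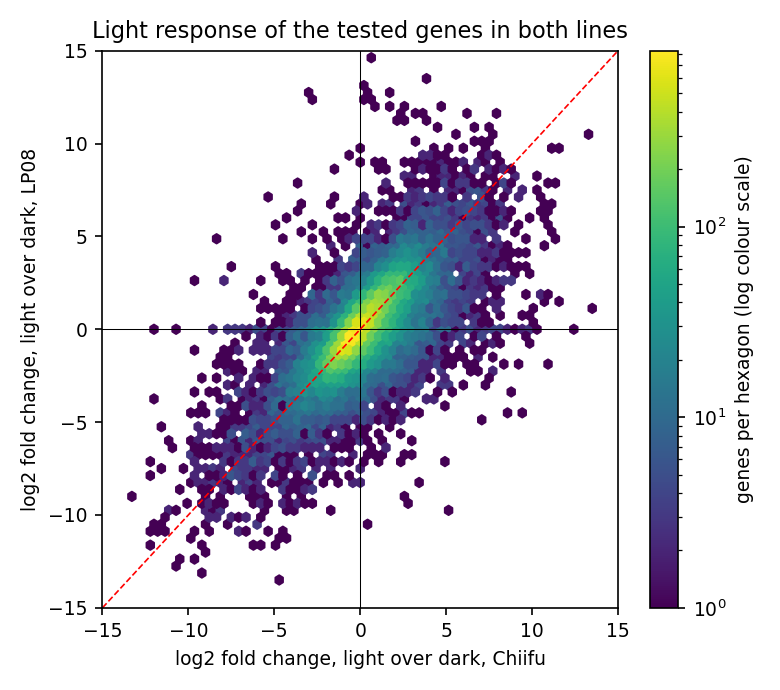
Log2 fold change of light over dark in Chiifu (x axis) against LP08 (y axis) for 31239 tested genes, with the number of genes per hexagon on a log colour scale and a dashed line of equal response. The density of genes follows the line (r = 0.71), with arms of genes near 0 in one line and large in the other.

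The second question was whether the lines responded differently. The test of the difference called 9121 genes, 4631 higher and 4490 lower in LP08. For some of the genes given by ID, such a call rested on a few reads against none, as described further below. How many of the 9121 calls, or of the classes they are split into, rest on such reads was not tested. By at least 2-fold, 2887 were higher and 3379 lower, which turned to 3282 and 3100 with DESeq2 size factors. The balance of all called genes also depended on the scaling, with 5288 higher and 4034 lower with DESeq2 size factors and 3901 and 4848 with library totals. More genes were also lower than higher with limma-voom (4613 and 4816), without Chiifu light replicate 1 (4085 and 4194) or 3 (3412 and 3486), and without LP08 light replicate 2 (3981 and 4044) or 3 (3593 and 3814). Among the 9121 genes, 3963 moved in the same direction in both lines, and the change was larger in LP08 for 2577 and larger in Chiifu for 1386. A further 1927 were called in Chiifu alone, 2271 in LP08 alone, 898 in opposite directions and 62 in neither line. Among genes that met the rule for naming, Bra013007 and Bra016075 had the most positive fitted difference. The fitted value of Bra016075 depends on the prior count, because it had groups with no reads. Bra013007 was at 241.2 ± 25.04 CPM in light LP08, and at 0.05 ± 0.03 in dark LP08, 0.09 ± 0.08 in light Chiifu and 0.63 ± 0.31 CPM in dark Chiifu (SD, n = 3, adjusted p = 2.32e-06). Bra016075 was at 15.2 ± 2.98 CPM in light LP08, with 3 reads in all in dark Chiifu and none in the other groups (adjusted p = 0.00115). Bra001086 had the most negative fitted difference among these genes, at 704.3 ± 434.8 CPM in light Chiifu and at 0.41 ± 0.16 or less in the other groups (adjusted p = 2.71e-05). Chiifu light replicate 2 was at 1205 CPM, against 491 and 417.3 CPM in the others. Bra003696 followed (adjusted p = 0.0243), but its call was lost in 5 of 22 settings. Among them were the fits without LP08 dark replicate 2 (log2 difference -7.08 against -12.41, adjusted p = 0.59), Chiifu dark replicate 2 (0.0517) or Chiifu dark replicate 3 (0.0629), and limma-voom (0.221). Over all alternatives its adjusted p was 0.000467 to 0.59.

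**Figure D4:**
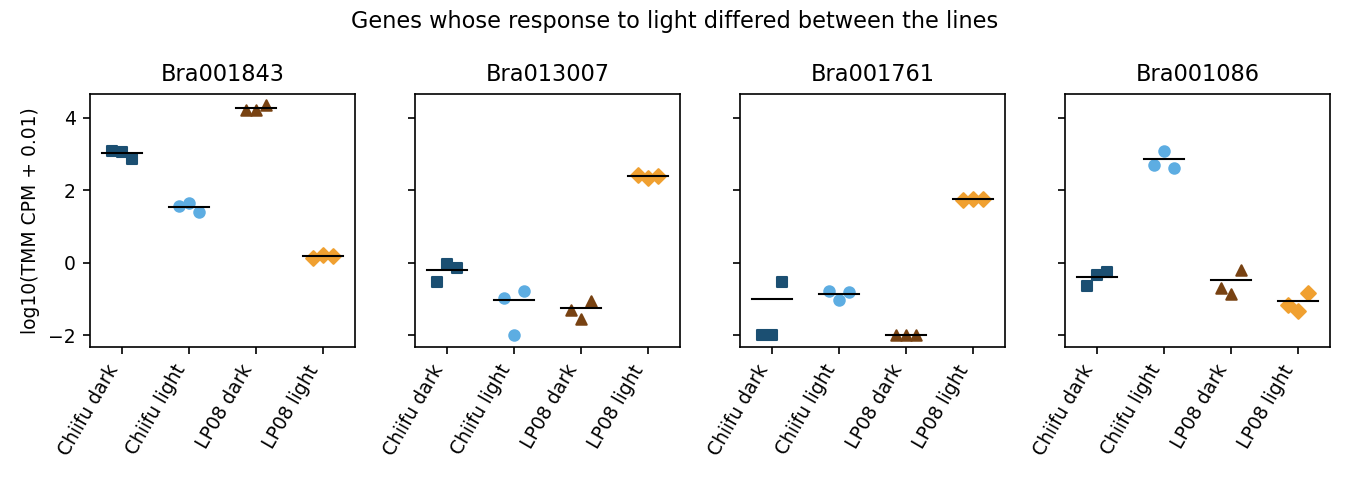
Expression as log10(TMM CPM + 0.01) (y axis) of 4 genes in the 4 groups (x axis); points are libraries and lines the mean CPM of the 3 libraries. Bra013007 and Bra001761 are high only in light LP08 (means 241.2 and 56.5 CPM), Bra001086 only in light Chiifu (704.3 CPM), and Bra001843 falls in light in both lines.

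The third question was how the lines differed under the same treatment. In light, 6670 genes were higher and 7819 lower in LP08, and 3098 and 5168 by at least 2-fold. In the dark, 7945 were higher and 8712 lower, and 4548 and 5356 by at least 2-fold. The balance in light depended on the scaling: 46.0% of called genes were higher in LP08 with TMM, 50.1% with DESeq2 size factors, 50.4% in the DESeq2 test and 32.5% with library totals, where the median log2 fold change of all genes was -0.19, against -0.02 with TMM. Line differences of at least 2-fold were called less often among abundant genes, though this was not tested. In light they were called for 45.7% of 5450 genes with a mean under 1 CPM and for 11.2% of 1746 genes with 100 CPM or more. In the dark the shares were 47.7% and 19.4%, and the light comparison in Chiifu had 50.4% and 56.8% for the same genes. The filter can keep a gene for its counts in a single group, so the low class can be enriched in genes that differ between groups. Bra014058 and Bra015167 had the largest excess in light LP08, at 32.5 ± 2.74 and 28.2 ± 2.13 CPM against no read in light Chiifu, at least 2290-fold and at least 1990-fold higher (adjusted p = 6.09e-08 and 1.22e-06). Bra005345 and Bra032570 were at 32.3 ± 5.11 and 28.3 ± 3.14 CPM in light Chiifu and had no read in light LP08, at least 1710-fold and 1500-fold lower (adjusted p = 1.67e-06 and 2.14e-08). In the dark, Bra014058 and Bra015167 were at 46.7 and 19.3 CPM in LP08 and 0.12 and 0.08 CPM in Chiifu. There Bra005345 and Bra032570 were at 6.9 and 28.3 CPM in Chiifu and 0.05 and 0.04 CPM in LP08. These differences were thus not particular to light. Whether a line lacks such genes, or its reads were lost in counting, was not tested for them.

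In the dark, Bra009323 and Bra014580 were at 30.6 ± 3.96 and 27.1 ± 4.54 CPM in LP08 with no read in Chiifu, at least 1850-fold and at least 1640-fold higher (adjusted p = 8.69e-08 and 3.18e-07). Bra037613 and Bra020483 were at 45.3 ± 12.6 and 39.3 ± 14.3 CPM in Chiifu with no read in LP08, at least 2370-fold and at least 2050-fold lower (adjusted p = 4.44e-08 and 5.07e-08). In light, Bra009323 and Bra014580 were at 8.37 and 3.53 CPM in LP08, with no read and 0.02 CPM in Chiifu. There Bra037613 and Bra020483 were at 29.4 and 8.31 CPM in Chiifu and 0.01 and 0.08 CPM in LP08. These differences were thus not particular to the dark. Line differences were called in both treatments for 9430 genes, in light only for 5059 and in the dark only for 7227. Of the genes called in either, 71.8% had a difference of the same sign in both. Of those called in both, 87.3% differed in the same direction (3615 higher and 4622 lower in LP08). Another 1193, or 788 to 1537 over left-out libraries, differed in opposite directions. Independent lists would share 1696, 2181 and 3849. The comparisons have no library in common, but they share the fit and the dispersion of each gene. The line differences correlated across genes with r = 0.76 and rho = 0.49. Reads of 77 genes were present in every Chiifu library at 1 CPM or more and absent from all 6 LP08 libraries, and 35 genes showed the opposite (exact two-sided binomial p for equal numbers = 8.98e-05). Their median levels were 3.89 and 3.67 CPM. The binomial test takes genes as independent, which they need not be, so its p can be too small.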

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

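The tests of mislabelling, of read loss and of RNA mixed in from another group were chosen, or took their present form, after results they bear on had been seen, and the alternatives without both libraries that stood apart, without ENSRNA features and with thinned libraries, and the levels raised to 1%, were added after seeing the data. For read loss, a first set of genes, picked on their level in Chiifu, had favoured genes lower in LP08 and was replaced after its result had been seen. For mixed-in RNA, a first measure over a handful of genes with no read in the sister libraries had been above 0 in Chiifu dark replicate 3 and was likewise replaced. The test of the difference itself called 9121 genes for their light response, so this count and 15 of the genes given by ID are listed here. Fitted differences of the response (LP08 minus Chiifu, log2) depend on the prior count where a group had no reads. They were 15.94 for Bra016075, 15.18 for Bra013007, 14.04 for Bra001761, 9.84 for Bra018521, 7.55 for Bra020483, 5.59 for Bra015167, 5.32 for Bra024080, 5.28 for Bra014058 and 4.49 for Bra027681. The negative ones were -12.78 for Bra001086, -12.41 for Bra003696, -8.71 for Bra001843, -6.87 for Bra005345, -6.25 for Bra014580 and -4.25 for Bra032570. Adjusted p-values of these 15 genes in the edgeR test of the difference ran from 7.94e-07 (Bra001843) to 0.0478 (Bra015167). Leaving out 1 library changed the value of 4 of them by over 1.5 times and ended their calls. Without Chiifu dark replicate 3 it was 8.77 for Bra001761 (adjusted p = 1) and 2.76 for Bra015167 (0.217). Without LP08 dark replicate 2 it was -7.08 for Bra003696 (0.59), and without Chiifu light replicate 3 it was -2.95 for Bra014580 (1).

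For 8 of these genes the fitted difference rested on a few reads against none: 21 and 12 in dark Chiifu for Bra014058 and Bra015167, 8 and 6 in dark LP08 for Bra005345 and Bra032570, 4 in light Chiifu for Bra014580, and 13, 8 and 8 in light LP08 for Bra020483, Bra027681 and Bra024080. Those reads were 0.0703% to 0.428% of the level in the gene's highest group, and so do not show that the light responses of these 8 genes differed. Only genes given by ID were examined in this way, so the share of such calls among all called genes is not known. When every level under 1% of the highest group was raised to that level, the difference was -0.52 for Bra014058 and -0.14 for Bra027681, both of the opposite sign, 0.00 for Bra032570, and -2.94 to 2.24 for the other 5. Bra014580, Bra005345 and Bra020483 were at -2.94, -2.23 and 2.24. For them this is the change in the line that expressed the gene, since both groups of the other line were raised to 1%. Of the remaining 7 genes, Bra016075, Bra013007 and Bra001761 were at 6.64 and Bra001086 at -6.64. This is the limit that the 1% sets for a gene with 1 group above it, so the sign of these 4 could not change and the values say nothing of stability. The others were at -5.42 (Bra003696), 5.06 (Bra018521) and -4.14 (Bra001843).

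Whether a chance division of the libraries could give that count was not decided. When line labels were exchanged within each light treatment, 2 of 100 drawn splits (of 200 possible) called as many genes, the real one among them with 9121. The other, with 17784, was the split that exchanges the lines completely in light, so that it adds up the line differences of both treatments, and it reflects the structure of the samples. The test planned for this was a poor one, because splits that mix the lines carry the differences of 14489 and 16657 genes between them into the spread, whether or not the light responses differ. For the 2-group comparisons the 10 splits are too few for a share under 0.05. Their other splits also mix the 2 groups, which carries the group differences into the spread. Few calls in those splits therefore decide nothing. In each of these comparisons 1 of 10 splits, the real one, gave as many genes: 14489 and 16657 for the lines in light and in dark, against at most 0 and 1 in the other splits, and 21086 and 21400 for light in Chiifu and in LP08, against at most 0 and 1.

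More genes were lower than higher in LP08 by at least 2-fold, and more were seen in Chiifu only. Larger Chiifu libraries are argued against for the genes seen in 1 line, because thinning to 48773088 counts each hardly changed their numbers. There were 79 in Chiifu only and 38 in LP08 only, against 77 and 35 without thinning. The exact binomial p after thinning was 0.000189, but it takes genes as independent. A candidate explanation is that LP08 reads were lost against a reference sequence closer to Chiifu, a loss that would be fixed for each gene. Among 23113 genes with a mean over both lines of at least 1 CPM in each treatment, the excess of lower over higher genes was 1071 in light (952 to 1135 over left-out libraries) and 541 in dark (446 to 703), so light exceeded dark by 530 with TMM scaling. With DESeq2 size factors the difference was 50, less than the ranges over left-out libraries, and with library totals 901. For both the 530 and the 541, read loss and a difference in expression or gene content cannot be told apart, because the first depends on the scaling and the genome the reads were counted on is not given in the sources used here.

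Chiifu dark replicate 3 and LP08 light replicate 3 had the lowest correlations with their groups. Mislabelling is argued against, since their mean correlation with their own group exceeded the highest with any other group by 0.134 and 0.139. Without ENSRNA features their correlations were 0.9656 and 0.9715, still the lowest 2 of the 12. Those features were only 151 of the 31239 genes, so leaving them out could hardly move a correlation. The test therefore cannot decide whether they had a part. RNA of a single other group mixed in, at most 0.557% and 0.263% by genes nearly silent in the sister libraries, could move 13083 and 13015 other genes by at most 0.0396 and 0.0188 (log2). For RNA of several groups together the limit would be higher, and it was not computed. Over those genes the libraries that stood apart differed from their sisters by a root mean square of 0.585 and 0.526, against at most 0.444 and 0.226 for the sisters. RNA mixed in from a single group is thus argued against as the whole cause. What set them apart stays open, including a difference between plants or in RNA quality, which was not tested.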

How the results depend on the processing

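The settings with library totals, without ENSRNA features, without both libraries that stood apart, with thinned libraries and with low levels raised to 1% were chosen after seeing the data. All 5 comparisons kept each count of called genes, in each direction and at 2-fold, within 1.5 times under the alternatives run. With the replicate number as a block, which the libraries' deviations did not bear out as a pairing, the response difference had 4324 genes higher and 4212 lower, and no count moved by over 1.5 times. The block ended the response call of Bra015167 (adjusted p = 0.0681), Bra032570 (0.0532), Bra014580 (0.0702) and Bra027681 (0.0703), and no other call of a gene given by ID. The correlation of the light responses (r = 0.71, rho = 0.72) was 0.611 and 0.612 with no filter on low counts and 0.641 and 0.627 with DESeq2, and r was 0.750 with the stricter filter. The correlation of the line differences (r = 0.76) was 0.67 with no filter and 0.688 with DESeq2. The cause was not tested. The number of genes with opposite line differences in the 2 treatments (1193) was 788 to 1537 over left-out libraries, lowest without Chiifu light replicate 2 and highest without Chiifu dark replicate 3. Genes seen in 1 line only depended on the threshold by construction: with at most 1 count in place of 0 there were 117 for Chiifu, and with 5 CPM in place of 1 there were 11 for Chiifu and 3 for LP08. Of the 15 response calls given by ID, 8 were lost in at least 1 of 22 settings: Bra015167 in 15 (adjusted p 0.0115 to 0.234 over the 22), Bra027681 in 14 (0.00691 to 0.153), Bra032570 in 10 (0.0102 to 0.12), Bra005345 in 8 (0.000152 to 0.111), Bra014580 in 8 (0.000932 to 1), Bra003696 in 5 (0.000467 to 0.59), and Bra001761 (1.25e-06 to 1) and Bra018521 (1.85e-06 to 0.102) in 2, without Chiifu dark replicate 3 and without both libraries that stood apart. With levels under 1% of the highest group raised to it, the response difference changed sign for Bra014058 (-0.52) and Bra027681 (-0.14), by the removal of trace reads. In the 4 other comparisons no call of a gene given by ID was lost in the settings run. Of same-direction genes whose response differed, 57.1% to 70.3% had the larger change in LP08 over the left-out libraries, against 65.0% in the main analysis. With library totals 29.9% of genes that differed by at least 2-fold in light were higher in LP08, against 37.5% with TMM scaling. In light against dark in Chiifu the called genes also turned from more higher to more lower with the stricter filter (9558 and 9798), with DESeq2 (10804 and 11182) and with thinning (10388 and 10441), and those of the response difference with thinning (4448 and 4464) and without both libraries that stood apart. The gene list tests planned before the data were examined were not run, because the IDs could not be joined to the lists. Thinning to the smallest total left 14217 genes called between the lines in light, against 14489. Without both libraries that stood apart, 7244 genes were higher and 8261 lower in LP08 in light, 8902 and 9223 in the dark, 10992 and 10845 in light against dark in Chiifu, 10486 and 11421 in LP08, and 4704 and 5047 had a higher and a lower response in LP08.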

Other observations

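The tests of neighbouring IDs were written down before their results were seen, but the shuffles at distances of 10 to 20 were then redone over all pairs, because those first used covered only part of them. Expression by abundance class differed between the comparisons beyond what is described above. Among the 1746 genes with a mean of 100 CPM or more, 591 were higher and 517 lower by at least 2-fold in light in LP08, and 514 and 478 in Chiifu. Between the lines these genes were nearly balanced, with 94 higher and 102 lower in LP08 in light and 174 and 165 in the dark. Among the 5450 genes with a mean under 1 CPM, 1734 were higher and 1014 lower in light in Chiifu, and 903 were higher and 1588 lower in LP08 than in Chiifu in light. The splits were nearer to even for light in LP08 (1359 higher and 1207 lower) and for the lines in the dark (1239 higher and 1363 lower in LP08). Both of the less even splits favoured light Chiifu, the group with the largest libraries (mean total 70034296 counts). Whether library size had a part was not tested, because thinned libraries were not counted by abundance class.

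For each library, genes at 20 CPM or more in another group and under 1% of that level in the mean of its sister libraries were picked. Over all pairs of a library and another group, their median level was 0.063% to 0.675% of that in the other group. In Chiifu dark replicate 3 it was 0.557% of the level in light Chiifu, over 72 genes, of which 68 had reads there. Its sister libraries had similar values for light Chiifu, 0.481% in replicate 1 and 0.675% in replicate 2, so this was not particular to replicate 3.

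A hypothesis was that genes with consecutive Bra ID numbers differ together between the lines. The Spearman correlation of the line difference in light between the 24437 consecutive pairs was 0.0761, above the highest of 1000 shuffles (0.0191). The line difference in the dark was at 0.0685. The light response correlated as well, at 0.0922 in Chiifu, above the line difference in light, and at 0.0695 in LP08, below it. At ID distances of 10 to 20 the correlation of the line difference was 0.00554 in light, above the highest of the shuffles (0.00539) by less than their SD (0.0019), and 0.00492 in the dark, within its shuffles (highest 0.0067). Most of the signal at consecutive IDs was thus gone at that distance. Whether reads shared between adjacent gene models gave it, or genes that differ together over longer stretches add to it, cannot be told apart, because the margin at 10 to 20 is within the spread of the shuffles and positions were not used here.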
